A study of Danio rerio with 96 samples.

How the data were processed

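DNA methylation was measured in 96 libraries from dissected heads of zebrafish larvae at 5 days post-fertilisation, in 4 groups of 24 defined by genotype (wild-type or glucocorticoid receptor mutant) and treatment (0.2% ethanol or 100 µM betamethasone). Per the labels' protocols, DNA was converted with bisulfite, 100 pg of converted DNA entered a first PCR of 40 cycles with primers that held 25 to 30 bp of amplicon-specific sequence, the products of each sample were pooled, barcoded in a second PCR and sequenced as 150 bp read pairs. Per the submitters' processing notes, FastQC, cutadapt and BS-Seeker2 were used with build GRCz10. Versions, settings, any step that removed reads and the list of targets are not given in the sources used here.

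The authors deposited 1 file of cytosine calls per library. Each listed cytosine had a strand and sequence context, a methylation level as a fraction with 2 decimals, a count of reads called methylated and a count of all reads. The deposited fraction was checked against the ratio of the deposited counts and differed by more than rounding at 0 cytosines, and 0 cytosines had more methylated than total reads. The counts, not the fractions, were used throughout. The highest count at any cytosine was 8088, and 89 libraries reached at least 8000, so the counts of the deepest amplicons end near the same value in most libraries.

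Groups and replicate numbers were taken from the labels. A target amplicon was a run of cytosines no more than 100 bp apart, each with at least 30 reads in at least 48 of the 96 libraries. This rule gave 8 amplicons with CpGs and 1 region without a CpG (chromosome 12, 3992909 to 3992934), which was left out. A CpG was tested where at least 10 larvae of each group had at least 30 reads, which held for 50 CpGs. For an amplicon, reads were summed over its tested CpGs per larva, and larvae missing any of these CpGs were left out. CpGs within 30 bp of an amplicon end, where a base may come from a primer, were kept. Of the CpGs named in the text, 41099447, 27961568, 4079376, 8404225, 14499697 and 8404240 lie there. Of the 96 libraries, 95 had at least 1 CpG at this depth and 63 had all 50; betamethasone-treated wild-type library 2 held 19 cytosine calls and gave no value. Each library was counted as 1 larval head. The labels do not give clutches, plates or batches, and p-values measure only the spread between these libraries. Reads are PCR copies without molecular identifiers, so precision computed from read depth covers counting error only. The errors given are SDs between larvae or SEs of differences of group means.

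Methylated reads out of all reads were compared by beta-binomial regression with 1 observation per larva and a two-sided likelihood ratio test, for 4 pairs of groups and for the genotype by treatment interaction on the logit scale. Adjusted p-values follow Benjamini-Hochberg over all CpGs, or all amplicons, of a comparison, with a threshold of 0.05. Differences are differences of unweighted group means in percentage points. The number of larvae with a direction is the number of the first-named group on that side of the other group's median. Non-CpG methylation, which includes incomplete conversion, was taken over cytosines more than 30 bp from an amplicon end. CpG methylation outside the amplicons was summed per library with at least 100 such reads. Both were compared by two-sided permutation tests with 100000 resamples, adjusted over the 4 pairs of groups. The work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

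The test was checked on simulated data with the depths and levels of the wild-type betamethasone and wild-type control libraries. Simulated larvae were independent and drawn from a beta-binomial distribution, the model of the test itself, and shifts ran towards the middle of the scale. The check therefore favours the beta-binomial test and does not cover libraries that resemble each other. Of 320 simulated unchanged CpGs, 4.06% had p below 0.05 by the beta-binomial test and 12.2% by a quasi-binomial F test. Of 160 CpGs per size, shifts of 5, 10 and 20 percentage points were found at p below 0.05 in 32.5%, 63.8% and 91.9%.

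Before the data were examined, these alternatives were set: a minimum of 10, 100 or 1000 reads, a permutation test of equally weighted larvae, a quasi-binomial F test weighted by reads, libraries above 2% non-CpG methylation left out, CpGs below 1% or above 99% left out, the replicate number as a block, and other ways to sum the non-CpG and off-amplicon levels. Chosen after seeing the data were 4 more. In the first, libraries of 1 group with matching CpG profiles at an amplicon (chi-square per CpG below 4, at least 500 reads at each CpG in both) were counted once. In the second, 4 libraries whose closest matches at 3 or more amplicons all lay in another group were left out. In the third, runs of 4 neighbouring replicate numbers were averaged to 6 values per group and compared by an exact permutation test, whose smallest p is 0.00217; for the interaction, residuals of the additive fit to the run means were permuted with 100000 resamples. In the last, the non-CpG cytosine with the highest level was left out.

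All 8 amplicons are named in the text. Of single CpGs, the rule set beforehand named up to 10 per comparison, those with adjusted p below 0.05 and the largest differences; a CpG outside it is said to be so. Gene lists set beforehand (glucocorticoid axis, activity-regulated genes, glutamate receptors and transporters, DNA methylation machinery, serotonin and dopamine genes) were not applied, because no annotation of GRCz10 was used here and the genes at the amplicons were not named. Coordinates are 1-based.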

Results

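CpG methylation was measured by bisulfite amplicon sequencing, in which unmethylated cytosines are read as T and methylated cytosines as C, in heads of zebrafish larvae at 5 days post-fertilisation. The larvae were wild-type or carried a mutant glucocorticoid receptor (GR), the nuclear receptor that binds cortisol. They were kept in 0.2% ethanol as control or in 100 µM betamethasone, a synthetic glucocorticoid that binds GR. Each of the 4 groups held 24 libraries. The median number of cytosine calls, reads summed over all cytosines, was 1260744 in wild-type control, 1309557 in wild-type betamethasone, 1240634 in GR mutant control and 1117623 in GR mutant betamethasone libraries. Single libraries ranged from 19 calls, in 1 wild-type betamethasone library that gave no CpG value, to 2009599. The shallowest library with values held 13422 calls.

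The data covered 50 CpGs in 8 amplicons of 112 to 225 bp (1-based positions, build GRCz10 per the submitters' processing notes). Their genes are not named, because no annotation of that build was used here. The amplicons covered a wide range of levels. The most methylated was chromosome 6, 27961540 to 27961753 (4 CpGs, 28.0 Mb), at 96.4% ± 2.5 (SD, n = 76) over all larvae with a median depth of 199 reads. The amplicon on chromosome 2, 14499688 to 14499886 (10 CpGs, minus strand), had a level of 82.7% ± 6.10 (SD, n = 90) at 551 reads. On chromosome 8, 22488700 to 22488907 (3 CpGs) had 76.4% ± 11.3 (SD, n = 73) at 214 reads. A further chromosome 6 amplicon, 41099247 to 41099469 (4 CpGs, 41.1 Mb), had 70.2% ± 6.82 (SD, n = 94) at 7929 reads. The chromosome 3 amplicon, 25887983 to 25888164 (6 CpGs), had 65.8% ± 8.60 (SD, n = 91) at 241 reads. The last chromosome 6 amplicon, 49743949 to 49744115 (5 CpGs, 49.7 Mb), had 57.5% ± 27.3 (SD, n = 94) at 8012 reads. Chromosome 15, 4079178 to 4079402 (13 CpGs), had 56.2% ± 17.6 (SD, n = 95) at 8012 reads. The least methylated, chromosome 16, 8404129 to 8404240 (5 CpGs, minus strand), had 36.9% ± 7.86 (SD, n = 90) at 1442 reads. The levels on chromosomes 2 and 16 each include 1 CpG near an amplicon end with almost no methylated reads, 14499697 and 8404240, which lowers them.

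**Figure D1:**
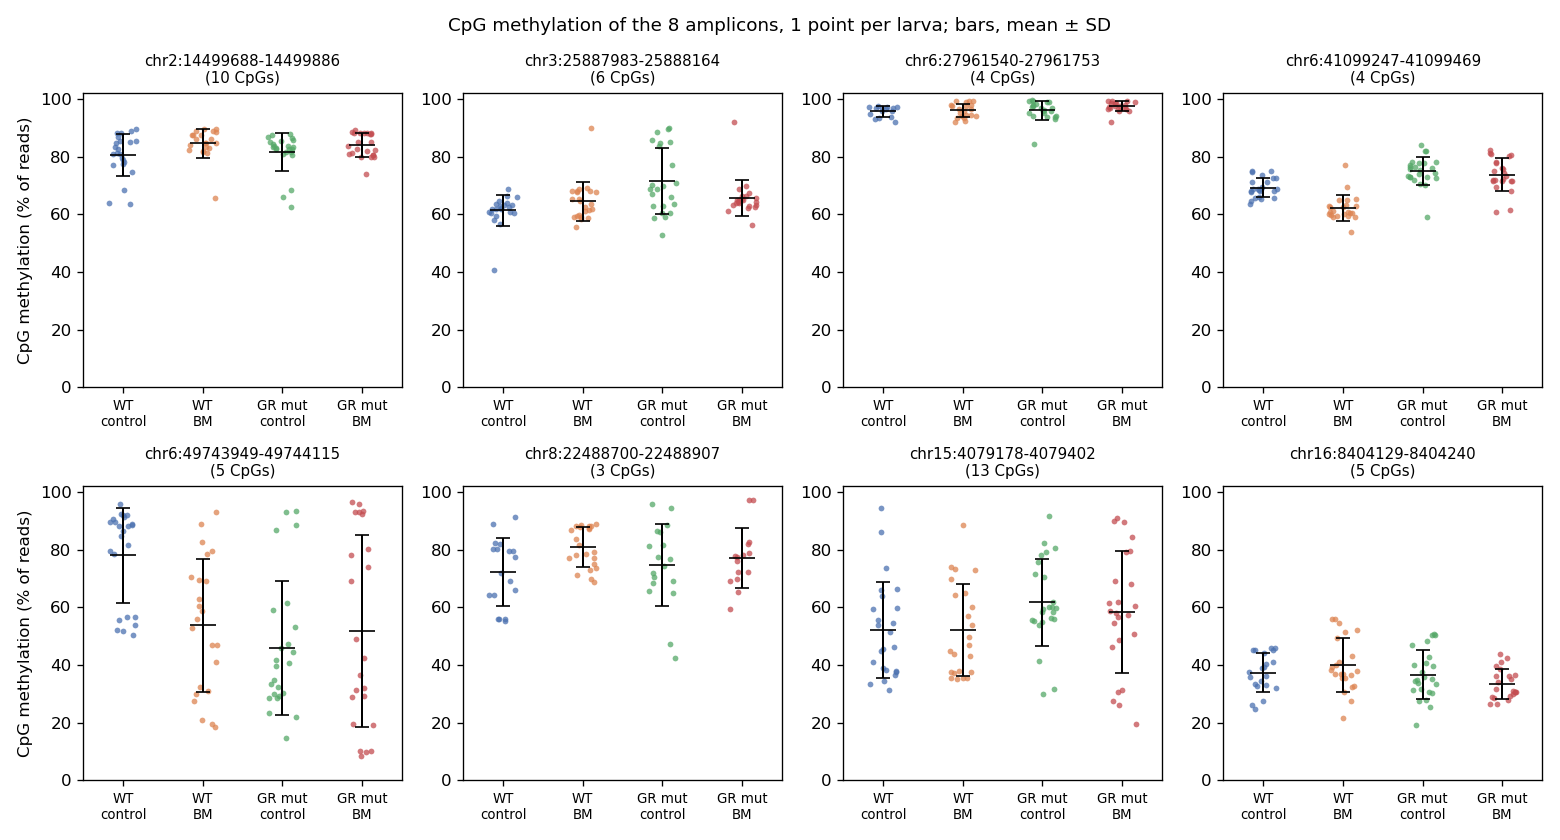
CpG methylation of the 8 amplicons (y axis, % of reads) in the 4 groups (x axis), 1 point per larva with bars at the mean ± SD. At 41.1 Mb of chromosome 6 the group means are 69.3%, 62.2%, 75.1% and 73.8% in the order drawn; at 49.7 Mb single larvae range from 8.29% to 96.4%.

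Over all larvae the SD was largest at the chromosome 6 amplicon at 49.7 Mb. Its 5 CpGs had nearly the same level within a larva, with a median range of 3.93 percentage points, while larvae ranged from 8.29% to 96.4%. In the counts of CpGs below, this amplicon therefore enters as up to 5 linked calls of nearly 1 measurement. Of its 94 larvae, 20 were below 30% and 15 were above 90%. Neighbouring replicate numbers often had like levels at single amplicons. Libraries with neighbouring numbers in a group matched within sampling noise (chi-square per CpG below 4, at least 500 reads) in 54 of 359 comparisons (15.0%). Other pairs of a group matched in 116 of 3743 (3.10%) and pairs across groups in 111 of 12116 (0.916%). Of 922 pairs of a group compared at 3 or more amplicons, 0 matched at all of them. Each library was counted as 1 replicate in the tests that follow, although the matches of neighbouring numbers go against full independence.

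**Figure D2:**
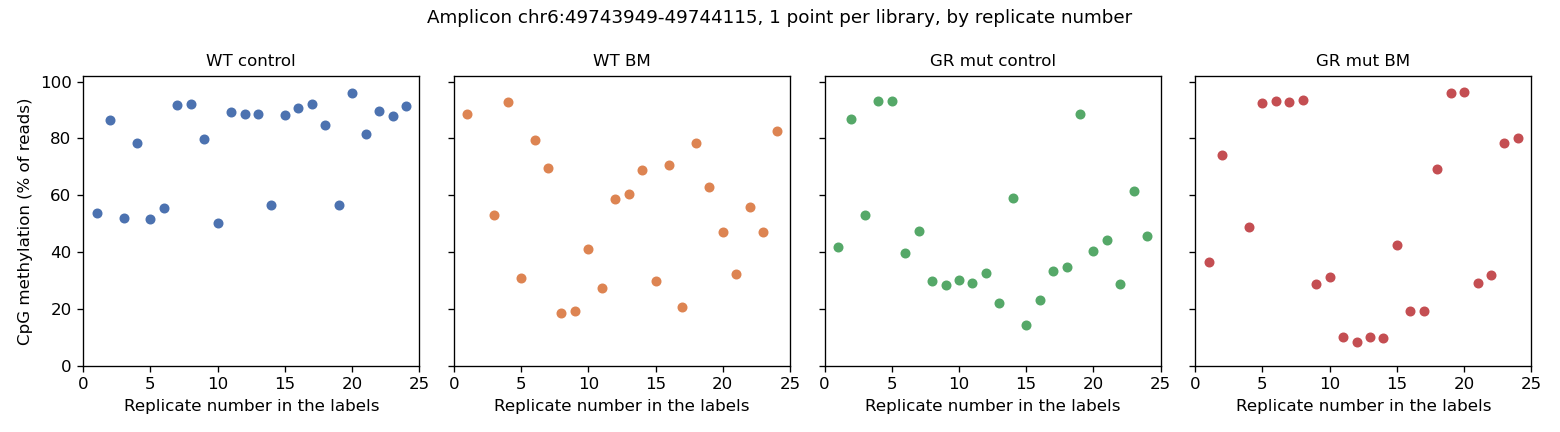
CpG methylation at chromosome 6, 49743949 to 49744115 (y axis, % of reads) by the replicate number in the labels (x axis), 1 point per library and 1 panel per group. In GR mutant betamethasone libraries, runs of neighbouring numbers sit at like levels, the lowest at 8.29% and the highest at 96.4%.

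The first comparison asked whether betamethasone exposure went with a methylation difference in wild-type larvae. Methylation fell at both deeply covered chromosome 6 amplicons and rose on chromosome 8. At 41.1 Mb of chromosome 6 the level fell from 69.3% ± 3.32 (SD, n = 24) in control to 62.2% ± 4.42 (SD, n = 23) in betamethasone larvae, and 21 of 23 betamethasone larvae lay below the control median. At 49.7 Mb it fell from 78.1% ± 16.5 (SD, n = 24) to 53.8% ± 23.2 (SD, n = 23), again with 21 of 23 larvae below. On chromosome 8 it rose from 72.3% ± 11.8 (SD, n = 18) to 80.9% ± 6.94 (SD, n = 22), with 17 of 22 larvae above. The differences were -7.07 percentage points (SE 1.14, adjusted p = 1.09e-06), -24.3 (SE 5.88, adjusted p = 0.000529) and 8.59 (SE 3.15, adjusted p = 0.0290) by the beta-binomial test. The other 5 amplicons did not pass. The nearest, on chromosome 2, was at 80.6% ± 7.35 (SD, n = 23) in control and 84.7% ± 5.12 (SD, n = 21) in betamethasone larvae (difference 4.09, SE 1.90, adjusted p = 0.0764, higher in 19 of 21). By the quasi-binomial test the chromosome 2 and chromosome 3 amplicons passed as well, with differences of 6.51 (adjusted p = 0.00357) and 11.2 (adjusted p = 0.00137).

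Of the 50 CpGs, 11 passed in wild-type larvae, 8 lower and 3 higher with betamethasone, and 14 had an unadjusted p below 0.05. All 5 CpGs at 49.7 Mb fell, by 23.1 to 25.4 percentage points. At 41.1 Mb all 4 CpGs were lower and 3 passed. Position 41099447 went from 86.3% ± 4.15 (SD, n = 24) to 74.3% ± 7.68 (SD, n = 23), lower in 22 of 23 larvae (adjusted p = 3.73e-06). It lies within 30 bp of the amplicon end, where a base may come from a primer. Position 41099291 went from 86.7% ± 4.07 (SD, n = 24) to 81.3% ± 4.96 (SD, n = 23), lower in 20 of 23 (adjusted p = 0.00178). The remaining CpG of that amplicon, 41099385, stood far below its neighbours, at 10.7% ± 11.4 (SD, n = 24) in control and 3.40% ± 5.85 (SD, n = 23) in betamethasone larvae (difference -7.30, SE 2.62). It did not pass by the beta-binomial test (adjusted p = 0.201) but passed by the permutation test (0.0281), the quasi-binomial test (0.0238) and with the replicate number as a block (0.0194). The chromosome 8 difference lay at position 22488829, which rose from 43.2% ± 33.8 (SD, n = 18) to 77.8% ± 22.7 (SD, n = 22), higher in 18 of 22 larvae (adjusted p = 0.00178). Position 25888054 on chromosome 3 rose by 8.95 (SE 2.99, adjusted p = 0.0101, higher in 17 of 23), and 27961568 at 28.0 Mb of chromosome 6 by 5.24 (SE 1.67, adjusted p = 0.000531, higher in 19 of 20). Position 27961568 also lies within 30 bp of an amplicon end. By the quasi-binomial test, which weights larvae by reads, 25888054 rose by 23.6 (adjusted p = 6.49e-05). The chromosome 8 amplicon no longer passed with matching libraries counted once (difference 4.96, adjusted p = 0.225) or with runs of 4 neighbouring numbers averaged (difference 8.29, adjusted p = 0.133), and 41099291 no longer passed with matching libraries counted once (adjusted p = 0.0705). By the exact permutation test of the 6 run means per group, 0 of 50 CpGs passed, 12 had an unadjusted p below 0.05 and the lowest adjusted p was 0.0541, while the smallest p that test allows is 0.00217. The differences stayed about as large, at -24.5 for 49743996, 33.4 for 22488829, -11.9 for 41099447 and 8.76 for 25888054.

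In GR mutant larvae the same exposure gave 0 of 8 amplicons past the threshold by the beta-binomial test, and 1 with an unadjusted p below 0.05. The level at 41.1 Mb of chromosome 6 was 75.1% ± 4.91 (SD, n = 24) in control and 73.8% ± 5.71 (SD, n = 23) in betamethasone larvae (difference -1.27, SE 1.56, adjusted p = 0.652, lower in 14 of 23). At 49.7 Mb it was 45.9% ± 23.3 (SD, n = 24) and 51.8% ± 33.4 (SD, n = 23), a difference of 5.94 (SE 8.43, adjusted p = 0.652, higher in 12 of 23). The chromosome 3 amplicon had the smallest p, at 71.7% ± 11.4 (SD, n = 23) in control and 65.6% ± 6.32 (SD, n = 23) in betamethasone larvae (difference -6.02, SE 2.73, unadjusted p = 0.0252, adjusted p = 0.201, lower in 21 of 23). The permutation test of equally weighted larvae also called 0 amplicons. The quasi-binomial F test called 1, on chromosome 8, with a difference of 13.2 (adjusted p = 0.0159) against 2.44 (SE 4.30) in the beta-binomial comparison.

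Of the 50 CpGs, 1 passed in GR mutant larvae and 8 had an unadjusted p below 0.05. Position 25888127 on chromosome 3 fell from 96.4% ± 2.05 (SD, n = 23) to 93.7% ± 3.04 (SD, n = 23), by 2.65 percentage points (SE 0.765, adjusted p = 0.00943), lower in 21 of 23 larvae. Its median depth was 4475 reads in control and 132 in betamethasone larvae. It no longer passed by the permutation test (adjusted p = 0.0640), the quasi-binomial test (0.825), with the replicate number as a block (0.132), with libraries above 2% non-CpG methylation left out (0.0576), with matching libraries counted once (0.0570) or with run means (0.217).

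The comparison of genotypes without betamethasone gave the largest number of CpGs past the threshold by the beta-binomial test, though not by the quasi-binomial test (19, against 20 for betamethasone in wild type). GR mutant controls were higher than wild-type controls on chromosome 3 and at 41.1 Mb of chromosome 6, and lower at 49.7 Mb. At 49.7 Mb the level was 45.9% ± 23.3 (SD, n = 24) in mutant and 78.1% ± 16.5 (SD, n = 24) in wild-type controls, a difference of -32.2 (SE 5.82, adjusted p = 3.37e-05), and 21 of 24 mutants lay below the wild-type median. At 41.1 Mb it was 75.1% ± 4.91 (SD, n = 24) against 69.3% ± 3.32 (SD, n = 24), a difference of 5.82 (SE 1.21, adjusted p = 3.37e-05), higher in 23 of 24. On chromosome 3 it was 71.7% ± 11.4 (SD, n = 23) against 61.4% ± 5.34 (SD, n = 22), a difference of 10.3 (SE 2.64, adjusted p = 0.000452), higher in 18 of 23. Median depth on chromosome 3 was 4475 reads in mutant and 148 in wild-type controls. The quasi-binomial test, which weights larvae by reads, gave a chromosome 3 difference of 20.2, and the call was lost with run means (difference 9.89, adjusted p = 0.0693). Chromosome 16 passed by the quasi-binomial test (-5.11, adjusted p = 0.0271), and chromosome 8 without libraries above 2% non-CpG methylation (12.4, adjusted p = 0.0137).

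Of the 50 CpGs, 18 passed between the control groups, 11 higher and 7 lower in mutants, and 21 had an unadjusted p below 0.05. All 5 CpGs at 49.7 Mb were lower, by 31.4 to 33.6 percentage points. On chromosome 3, 3 of 6 CpGs passed, each higher. The largest difference there was at 25888047, with 46.4% ± 26.0 (SD, n = 23) in mutant and 21.6% ± 9.18 (SD, n = 23) in wild-type controls (difference 24.8, SE 5.76, adjusted p = 0.00383, higher in 18 of 23). Position 25888054 was at 80.4% ± 10.2 (SD, n = 23) against 65.02% ± 9.76 (SD, n = 23), higher in 22 of 23 (adjusted p = 1.22e-05). By the quasi-binomial test, which weights larvae by reads, the differences were 48.0 at 25888047 and 34.0 at 25888054. At 41.1 Mb, 3 of 4 CpGs passed, higher by 1.94 to 7.90 percentage points; 41099385 was higher by 6.93 (adjusted p = 0.116) and passed at a minimum of 1000 reads (7.25, adjusted p = 0.0499). On chromosome 15, where the whole amplicon did not pass (61.8% ± 15.1 against 52.1% ± 16.8, SD, n = 24 each, adjusted p = 0.150) except with run means (difference 9.69, adjusted p = 0.0462), 2 of 13 CpGs passed, each higher. These were 4079376 (difference 20.3, SE 5.72, adjusted p = 0.00432, higher in 21 of 24) and 4079277 (difference 17.5, SE 5.90, adjusted p = 0.0315, higher in 22 of 24). Position 4079376 lies within 30 bp of the amplicon end. Some sequences read elsewhere in the genome resembled this amplicon. At its position 4079298 a mean of 18.0% of reads in wild-type and 6.88% in mutant controls gave no cytosine call. Whether reads of other sequences entered these CpG levels was not tested. At 28.0 Mb of chromosome 6, 3 of 4 CpGs passed, 2 higher and 1 lower, and on chromosome 16, 1 of 5 passed, which was lower. Position 22488753 on chromosome 8 was at 88.7% ± 8.39 (SD, n = 18) against 78.5% ± 10.2 (SD, n = 18), higher in 16 of 18 (adjusted p = 0.0147). The latter difference was -0.275 by the quasi-binomial test and no longer passed with the replicate number as a block (6.41, adjusted p = 0.176) or with run means (8.67, adjusted p = 0.187). Position 4079277 no longer passed with matching libraries counted once (adjusted p = 0.0686) or without libraries above 2% non-CpG methylation (0.0839), and 25888047 not with run means (0.0637).

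**Figure D3:**
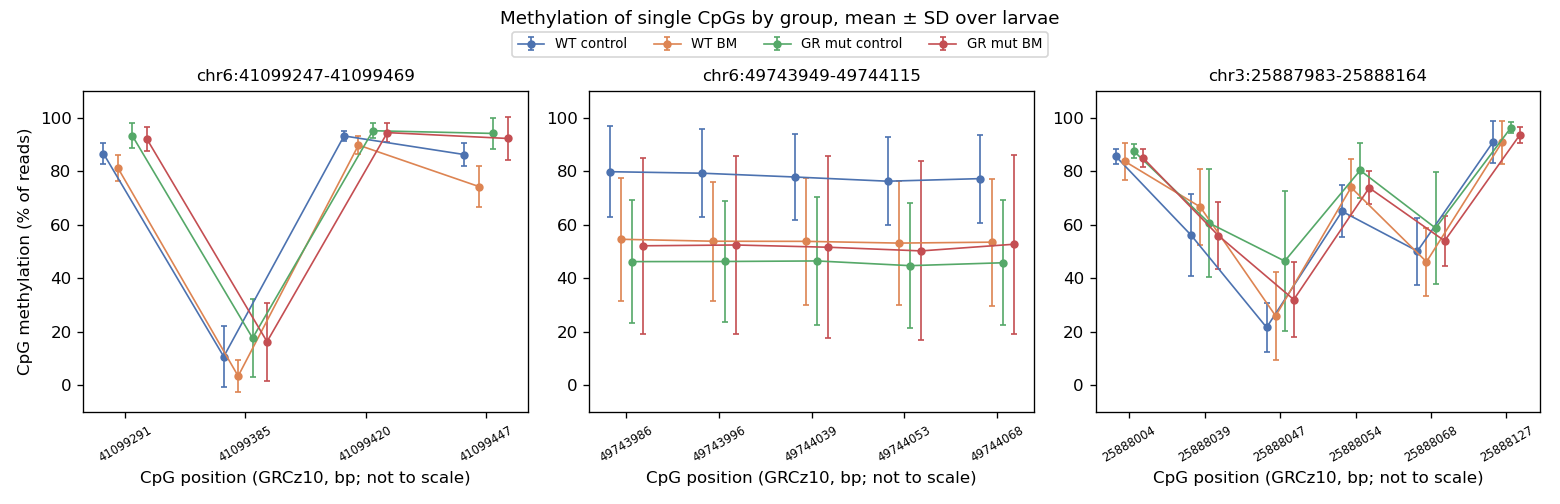
Methylation of single CpGs (y axis, % of reads) by position (x axis, evenly spaced) in 3 amplicons, mean ± SD over the larvae of each of the 4 groups. At 41.1 Mb of chromosome 6 position 41099385 lies at 3.40% to 17.6% between CpGs at 74.3% to 95.2%, while the 5 CpGs at 49.7 Mb have nearly equal means within each group.

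Among betamethasone-treated larvae, GR mutants were higher than wild type at 41.1 Mb of chromosome 6 and lower on chromosome 16. At 41.1 Mb the level was 73.8% ± 5.71 (SD, n = 23) in mutant and 62.2% ± 4.42 (SD, n = 23) in wild-type larvae, a difference of 11.6 (SE 1.505, adjusted p = 4.07e-09), higher in 22 of 23. On chromosome 16 it was 33.4% ± 5.22 (SD, n = 22) against 40.1% ± 9.29 (SD, n = 23), a difference of -6.63 (SE 2.23, adjusted p = 0.0224), lower in 17 of 22. At 49.7 Mb, where the control groups differed, the treated groups were at 51.8% ± 33.4 (SD, n = 23) and 53.8% ± 23.2 (SD, n = 23), a difference of -1.95 (SE 8.47, adjusted p = 0.965). Of the 50 CpGs, 5 passed and 12 had an unadjusted p below 0.05. All 4 CpGs at 41.1 Mb were higher in mutants, from 4.67 percentage points at 41099420 (SE 0.988, higher in 21 of 23) to 18.0 at 41099447 (SE 2.31, adjusted p = 1.54e-09, higher in 21 of 23). Among these, 41099385 was at 16.3% ± 14.6 (SD, n = 23) against 3.40% ± 5.85 (SD, n = 23), higher in 20 of 23 (adjusted p = 0.00546), and no longer passed with run means (0.130). On chromosome 16, 8404205 was at 44.6% ± 12.4 (SD, n = 22) against 60.0% ± 12.5 (SD, n = 23), lower in 18 of 22 (adjusted p = 0.00156). The chromosome 16 amplicon no longer passed at a minimum of 1000 reads (adjusted p = 0.115), with the replicate number as a block (0.0578), with matching libraries counted once (0.200) or with run means (0.121), and 8404205 not at 1000 reads (0.146) or with run means (0.170). By the quasi-binomial test the chromosome 8 amplicon was higher in mutants by 9.96 (adjusted p = 0.0191), against -3.78 (SE 3.05) in the beta-binomial comparison.

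The interaction asked whether the betamethasone difference itself differed between genotypes, and 3 of 8 amplicons passed, each with an adjusted p of 0.0205. At 41.1 Mb of chromosome 6 the betamethasone difference was -7.07 in wild-type and -1.27 in mutant larvae, so that the mutant difference was 5.80 percentage points higher (SE 1.93, n = 94). Without libraries above 2% non-CpG methylation it was 3.11 and did not pass (adjusted p = 0.382). This limit takes out 10 wild-type control, 2 wild-type betamethasone, 5 mutant control and 2 mutant betamethasone libraries, so it falls unevenly on the groups. At 49.7 Mb the differences were -24.3 and 5.94, 30.3 apart (SE 10.3, n = 94). On chromosome 3 they were 3.14 and -6.02, with the mutant difference lower by -9.16 (SE 3.28, n = 91), and by the quasi-binomial test it was -13.9 and did not pass (adjusted p = 0.110). Chromosome 8 (-16.4, adjusted p = 0.0461) and chromosome 16 (-8.12, adjusted p = 0.0463) passed only without libraries above 2% non-CpG methylation. Of the 50 CpGs, 7 passed and 14 had an unadjusted p below 0.05. They were 3 CpGs at 49.7 Mb with interactions of 30.7 to 31.6, 25888054 on chromosome 3 at -15.5 (SE 3.90, adjusted p = 0.00174), 8404205 and 8404225 on chromosome 16 at -14.0 each (SE 4.97 and 5.04), and 27961650 at 28.0 Mb of chromosome 6 at 9.20 (SE 2.77). The interaction at 8404205 was -4.86 at a minimum of 1000 reads (adjusted p = 0.657) and -6.74 by the quasi-binomial test (0.377). At 100 reads 8404205 and 8404225 did not pass (-11.2 and -12.03, adjusted p = 0.106 and 0.0902), nor with the replicate number as a block (-13.0 and -14.0, 0.0793 and 0.133). With the block 27961650 did not pass either (10.02, adjusted p = 0.156). Without libraries above 2% non-CpG methylation the 3 CpGs at 49.7 Mb kept 30.5 to 31.1 but did not pass (adjusted p = 0.0658 to 0.0706). All but 25888054 had the same adjusted p of 0.0401 and were lost together without the 4 libraries whose closest matches lay in another group and at a minimum of 10 reads, each of which left 1 CpG. The differences moved little: 49743996 was at 29.5 and 31.6, 27961650 at 9.22 and 8.13 and 8404205 at -12.4 and -12.8 in these settings. With matching libraries counted once 1 amplicon and 3 CpGs passed, while 41.1 Mb and chromosome 3 kept differences of 5.93 and -8.27 (adjusted p = 0.0523 and 0.0519). With run means and a permutation of residuals 0 of 8 amplicons passed (3 at an unadjusted p below 0.05) and 0 of 50 CpGs (7). The run means kept differences of 5.88 at 41.1 Mb, 29.3 at 49.7 Mb and -8.39 on chromosome 3 (adjusted p = 0.113 to 0.120), with 6 values per group. The 4 pairwise comparisons and the interaction use the same 4 groups and share their chance values.

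Methylation outside CpGs, in part a measure of incomplete conversion, was low in all groups. It was 1.93% ± 0.633 (SD, n = 24) in wild-type control, 1.64% ± 0.374 (SD, n = 23) in wild-type betamethasone, 1.31% ± 0.628 (SD, n = 24) in mutant control and 1.53% ± 0.450 (SD, n = 24) in mutant betamethasone libraries. Mutant controls were lower than wild-type controls by the permutation test (difference -0.622, adjusted p = 0.00472), and the other 3 differences did not pass (adjusted p = 0.114 to 0.388). Without 1 cytosine, 4079297 on chromosome 15, whose pooled level was 10.8%, that difference was -0.428 and did not pass (adjusted p = 0.125). The level of this cytosine was 18.9%, 18.9%, 7.22% and 3.46% by group in the order above, close to the share of reads without a call at the next position (18.0%, 17.8%, 6.88% and 2.29%). The non-CpG level, and the limit of 2% drawn from it, is therefore not taken as conversion alone. As an unweighted mean over cytosines, the wild-type betamethasone level was higher than control by 0.250 (adjusted p = 0.0378) instead of lower by -0.297.

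CpGs outside the amplicons, read at a median of 12686 to 36956 reads per library by group, had a mean level of 68.7% ± 21.0 (SD, n = 24) in wild-type control, 69.9% ± 12.1 (SD, n = 23) in wild-type betamethasone, 70.0% ± 15.5 (SD, n = 24) in mutant control and 79.3% ± 9.62 (SD, n = 24) in mutant betamethasone libraries. By permutation test the mutant betamethasone level was higher than in mutant controls by 9.31 (adjusted p = 0.0320) and higher than in wild-type betamethasone libraries by 9.48 (adjusted p = 0.0137). With the replicate number as a block neither passed (adjusted p = 0.0512 for both), and with at least 1000 such reads the former did not (8.60, adjusted p = 0.0512). The CpGs read were not the same in each library, with a median of 940 to 1286 per library by group. The differences may therefore come from which CpGs were read.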

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

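In this part, the tests of chance similarity, of a library entered more than once and of a single-locus variant were chosen only after the result was seen, as were the alternatives that count matching libraries once, leave out 4 libraries or average runs of 4 neighbouring numbers.

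The difference between betamethasone and control larvae was not the same in GR mutants and wild type at 3 amplicons, by the interaction test. The mutant difference minus the wild-type difference was -9.16 percentage points on chromosome 3, 5.80 at 41.1 Mb of chromosome 6 and 30.3 at 49.7 Mb. At 41.1 Mb it was 3.11 without libraries above 2% non-CpG methylation (adjusted p = 0.382), and on chromosome 3 -13.9 by the quasi-binomial test (adjusted p = 0.110), so neither passed in every planned setting. The same test picked out 7 CpGs. At 49.7 Mb these were 49743996, 49743986 and 49744068, with 31.6, 31.2 and 30.7 percentage points. The 5 CpGs of that amplicon correlated between larvae within groups with r of 0.9947 to 0.9975. These 3 are therefore nearly 1 measurement and do not stand apart from the other CpGs there. On chromosome 3, 25888054 had -15.5, on chromosome 16, 8404205 had -14.03 and 8404225 had -13.98, and at 28.0 Mb of chromosome 6, 27961650 had 9.20. With the means of runs of 4 neighbouring numbers, 0 of these amplicons or CpGs passed a permutation test of the residuals (3 amplicons and 7 CpGs at an unadjusted p below 0.05). The differences stayed about as large, at -8.39, 5.88 and 29.3 for the amplicons and 30.7 at 49743996, and the number of values fell to 6 per group.

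A further signal lay in reads that the CpG comparisons do not use. At position 4079298 of the chromosome 15 amplicon a share of the reads covering the neighbouring cytosine carried no cytosine call, as happens where a read holds a base other than C or T. This share was 18.0% ± 17.8 (SD, n = 24) in wild-type control, 17.8% ± 16.4 (SD, n = 23) in wild-type betamethasone, 6.88% ± 6.24 (SD, n = 24) in mutant control and 2.29% ± 2.69 (SD, n = 24) in mutant betamethasone libraries. By permutation test adjusted over 4 comparisons, it was lower in mutant than in wild-type controls (difference -11.2, adjusted p = 0.000300), lower in mutant than in wild-type betamethasone libraries (-15.5, adjusted p = 4.0e-05) and lower in mutant betamethasone than in mutant control libraries (-4.58, adjusted p = 0.00173).

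The lower methylation at 41.1 Mb of chromosome 6 in betamethasone-treated wild-type larvae was weighed against 4 technical explanations. The values argue against incomplete conversion, read depth and the libraries that match by the criterion used as the whole cause. They do not decide on libraries that share product without matching, or on mislabelled or mixed libraries. Counting matching libraries once left an adjusted p of 0.000118 by the beta-binomial test with 17 and 19 values in place of 23 and 24. The match takes reads as independent molecules, while larvae at this amplicon spread like a median of 34.6 reads. Libraries that shared product but differed by more than read counting were therefore not merged, so shared product was tested only in part. Leaving out the 4 libraries whose closest matches lay in another group left 1.64e-09. This comparison kept 22 and 23 values in that setting, a change too small to end the call, so mislabelled or mixed libraries were hardly tested. Non-CpG cytosines of the same amplicon differed by 0.110 percentage points (95% bootstrap interval -0.150 to 0.350), against -7.07 at its CpGs, which argues against incomplete conversion. They show only unmethylated cytosines left unconverted, so other faults of conversion or amplification were not tested. At a minimum of 1000 reads the adjusted p was 4.82e-06, which argues against the lower depth of wild-type controls (median 3312 reads against 7999). Also open is whether the groups were raised, converted or amplified separately, which the labels do not give, so a response to betamethasone is a hypothesis.

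Libraries with neighbouring replicate numbers matched at single amplicons in 54 of 359 comparisons, against a mean of 14.2 and a highest value of 34 when numbers were shuffled within groups, with p = 0.0001, the smallest that 10000 shuffles can give, so independent larvae that resemble each other by chance are unlikely as the cause. Of 922 pairs of a group 0 matched at every amplicon compared, which does not decide whether a larva was entered more than once, since the match takes reads as independent molecules and the spread between larvae at single CpGs was that of a median of 4.59 to 34.6 reads, so 1 larva amplified again need not match. The structure may add calls: dividing GR mutant betamethasone libraries into numbers 1 to 12 and 13 to 24 called 8 CpGs, against 1 for odd and even numbers and 2, 0 and 0 for the first division of the wild-type control, wild-type betamethasone and mutant control groups. Products shared between neighbouring wells in the first PCR and larvae of 1 clutch set side by side stay open, and neither was tested. No biological explanation was tested.

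For the chromosome 15 share, 2 explanations could not be told apart from others. Reads from other copies of a repeat placed at this amplicon might raise it, and within groups the share went up with the reads on like sequences of chromosomes 9 and 13 with a median Spearman rho of 0.442, but 2 of 4 groups passed the test where 3 had been asked for. A single-locus variant might be carried by different numbers of alleles, and 56.8% of libraries lay below 10%, at 35 to 65% or above 90%. This was between the bounds of 50% and 80% set for the test. The 3 ranges held 51, 2 and 1 libraries, and 40 of 95 lay between 10% and 35%. The score came mostly from the lowest range, which a low share of any cause fills, so it says little for a variant. A difference in parental fish between the genotypes stays open and untested.

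Chance was tested, with libraries taken as independent, by counting how many of 100 splits of the same libraries, the real one included, gave as many calls. In wild-type larvae with and without betamethasone chance can be excluded for CpGs (11 called, highest other split 7, 1 of 100 as large) and amplicons (3 called, highest other 2, 1 of 100). In GR mutant larvae it cannot be excluded for CpGs (1 called, highest other 5, 7 of 100). With 0 amplicons called there by the beta-binomial test (1 at an unadjusted p below 0.05), every split gives as many (100 of 100, highest other 3), so that count tests nothing. Between the control groups chance can be excluded for CpGs (18 called, highest other 1, 1 of 100) and amplicons (3 called, highest other 2, 1 of 100), and between the betamethasone groups as well (5 CpGs, highest other 2, and 2 amplicons, highest other 1, each 1 of 100). For the interaction, 1 of 100 splits, the real one, gave as many calls in the main setting (7 CpGs, highest other 3, and 3 amplicons, highest other 2). At a minimum of 10 reads 1 CpG was called, and without the 4 libraries also 1. With matching libraries counted once, 3 CpGs and 1 amplicon were called. Chance is therefore not excluded for the interaction. The matches of neighbouring numbers argue against independence, and dividing 1 group by number called 8 CpGs. Run means, which test order over 4 neighbouring numbers, called 13 CpGs and 3 amplicons between the control groups by the exact permutation test. Of these, 11 and 2 were among the main calls, while chromosome 3 was lost (adjusted p = 0.0693) and chromosome 15 gained (0.0462). Kept from the main calls were also 3 CpGs and 1 amplicon between the treated groups and 2 amplicons for betamethasone in wild type (41.1 Mb, adjusted p = 0.0173, and 49.7 Mb, 0.0346). For the calls kept, this goes against order within runs of 4 as the whole cause. Order over longer runs stays open, and the group whose division called 8 CpGs, mutant betamethasone, is 1 of the treated groups. Run means left 0 CpGs for betamethasone in wild type by the exact permutation test (12 at an unadjusted p below 0.05), and 0 CpGs and 0 amplicons for the interaction by a permutation of residuals (7 and 3). The differences stayed about as large with 6 values per group, such as -24.5 against -25.4 at 49743996 in wild type, so these losses do not show that order was the cause, and for these counts it stays open.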

How the results depend on the processing

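Counting matching libraries once, leaving out 4 libraries, averaging runs of 4 neighbouring numbers and leaving out the highest non-CpG cytosine were chosen only after the data were seen. 5 amplicon differences kept direction and significance under each of the 11 other settings: 41.1 Mb and 49.7 Mb of chromosome 6 for betamethasone in wild type and between control groups, and 41.1 Mb between treated groups. At a minimum of 10 reads the interaction called 1 CpG in place of 7. At 100 reads, differences that had not passed turned at 28.0 Mb of chromosome 6, to -0.0631 for betamethasone in wild type and -0.193 between control groups. At 1000 reads, with 27 CpGs and 4 amplicons left to test, chromosome 16 turned to -0.0397 for betamethasone in wild type, the treated groups differed at 1 amplicon in place of 2 and betamethasone in mutants at 0 CpGs in place of 1. The permutation test of equally weighted larvae called 0 CpGs for betamethasone in mutants and 11 for the interaction in place of 7. The quasi-binomial F test gave 12.2% of unchanged CpGs a p below 0.05 in the simulation, which was drawn from the model of the beta-binomial test. It called 20 CpGs in place of 11 and 5 amplicons in place of 3 for betamethasone in wild type. In mutants it called 2 CpGs in place of 1 and 1 amplicon in place of 0. It called 13 CpGs in place of 5 between treated groups and 12 in place of 7 for the interaction. It turned the interaction on chromosome 8 to 2.48 and on chromosome 15 to 1.71, betamethasone in wild type at 28.0 Mb to -0.665 and on chromosome 15 to -2.86, the control groups at 28.0 Mb to -0.115 and at 22488753 to -0.275, and the treated groups on chromosome 8 to 9.96 and at 49.7 Mb to 0.956; the cause was not tested. Without libraries above 2% non-CpG methylation, 46 CpGs and 7 amplicons could be tested, betamethasone in mutants called 0 CpGs and the interaction 4, and values that had not passed turned on chromosome 15 in wild type (-1.19), at 49.7 Mb between treated groups (0.674) and on chromosome 8 in mutants (-0.988). The interaction at 41.1 Mb dropped to 3.11 and no longer passed, and passes were gained for the interaction on chromosomes 8 (-16.4) and 16 (-8.12) and between control groups on chromosome 8 (12.4). Of the 19 libraries left out here, 10 were wild-type controls. With matching libraries counted once, and so fewer values, the treated groups differed at 1 amplicon, betamethasone in mutants at 0 CpGs, the interaction at 1 amplicon in place of 3 and 3 CpGs in place of 7, and the chromosome 16 value between control groups turned to 0.547. Without the 4 libraries the interaction called 1 CpG. With runs averaged, and so 6 values per group, betamethasone called 0 CpGs in wild type in place of 11 and 0 in mutants, the treated groups 3 CpGs in place of 5 and 1 amplicon in place of 2, and the interaction 0 CpGs and 0 amplicons, while chromosome 15 in wild type turned to -0.0287 and chromosome 8 between control groups to -0.676. Leaving out CpGs below 1% or above 99% changed none of 73 single-amplicon and single-CpG results, the permutation test kept 72 of 73 and a minimum of 10 reads 67 of 73.

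The replicate numbers do not pair the libraries. Of 141 pairs with the same number, 46 correlated above 0.1 (median r = -0.0215, range -0.630 to 0.738), and 7 of 95 libraries correlated best with their own number. With the number as a replicate block, CpG calls were 13, 1, 15, 5 and 9 for betamethasone in wild type, in mutants, the control groups, the treated groups and the interaction, against 11, 1, 18, 5 and 7, of which 11, 0, 13, 5 and 4 were the same CpGs. The treated groups differed at 1 amplicon in place of 2, and the off-amplicon differences kept 9.31 and 9.50 but not the threshold. Values that had not passed turned under the block for the interaction on chromosome 8 (1.85) and at 28.0 Mb (-0.0518), the treated groups on chromosome 2 (0.0313), the control groups on chromosome 8 (-2.61) and at 28.0 Mb (-0.0621), and betamethasone in wild type on chromosome 15 (-0.568).

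For non-CpG methylation, an unweighted mean over cytosines turned the wild-type betamethasone difference to 0.250 and brought that between treated groups past the threshold (-0.398). Without the highest cytosine the control difference was -0.428 and no longer passed, and that between treated groups turned to 0.0229. For off-amplicon CpGs, at least 1000 reads left 8.60 for betamethasone in mutants, past no threshold.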

Other observations

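In this part, the matching of libraries was looked at only after the data were seen.

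Some sequences read elsewhere in the genome resembled the chromosome 15 amplicon. Of 58 off-target regions covered in 10 or more libraries, 6 held at least 10 CpGs and were picked by that alone. Their mean CpG methylation ran from 77.7% to 99.3%, above the 56.2% ± 17.6 (SD, n = 95) of the amplicon itself. Spacing was compared at 14 positions of the amplicon, its 13 CpGs and the non-CpG cytosine 4079297. Among the regions were chromosome 13, 32058289 to 32058498, at 89.2% ± 2.96 (SD, n = 32), and chromosome 9, 27415266 to 27415475, at 89.3% ± 2.71 (SD, n = 34), each with 13 of 14 positions at that spacing. The others had 12 (chromosome 7), 10 (chromosome 9, 16020483), 9 (chromosome 20) and 5 (chromosome 15, 11620368), so the last resembled the amplicon little. A chromosome 7 region, 35168942 to 35169151, was at 99.3% ± 0.951 (SD, n = 10). The region at 16020483 to 16020647 of chromosome 9 was at 77.7% ± 8.93 (SD, n = 29). A region was read in 0 to 16 libraries of a group, and its levels were not compared between groups.

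The amplicons differed in how their CpGs varied, here over CpGs with a mean of 1% to 99%. At 49.7 Mb of chromosome 6 the CpGs of a larva differed by a median of 3.93 percentage points, against 85.9 at 41.1 Mb, 65.1 on chromosome 3, 53.6 on chromosome 15, 34.3 on chromosome 8, 28.9 on chromosome 16, 25.1 on chromosome 2 and 6.47 at 28.0 Mb. At 41.1 Mb 41099385 had a mean of 3.40% to 17.6% by group, and the other 3 CpGs 74.3% to 95.2%. On chromosome 8, 22488829 had the largest SD over larvae, 31.2, against 17.4 and 12.7 at the other 2 CpGs. The CpG at 14499697 on chromosome 2 and the CpG at 8404240 on chromosome 16 had pooled levels of 0.00980% and 0.0136%. Both lie within 30 bp of an amplicon end and far below the non-CpG group means of 1.31% to 1.93%. Their bases are therefore likely to come from primers and are not taken as methylation of the larvae, although both were among the 50 tested CpGs.

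Within groups, the share of reads without a call at 4079298 was set against the reads on the chromosome 9 and 13 copies relative to the amplicon, 4 relations in all. Spearman's rho was 0.341 in wild-type control (permutation p = 0.103, adjusted p = 0.138), 0.543 in wild-type betamethasone (p = 0.00839, adjusted 0.0168), 0.310 in mutant control (p = 0.139, adjusted 0.139) and 0.774 in mutant betamethasone libraries (p = 6.0e-05, adjusted 0.000240). Pearson's r was 0.137 (permutation p = 0.522), 0.326 (p = 0.120), 0.522 (p = 0.00900) and 0.751 (p = 0.000490) in the same order. Without the 2 libraries farthest from the median of the copy reads it was 0.264, 0.448, 0.256 and 0.826, so much of the Pearson correlation in mutant controls came from those 2 libraries.

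In 4 libraries the closest matches at 3 or more amplicons all lay in another group. Wild-type control 20 and mutant betamethasone 19 matched each other at 3 of 3 amplicons compared, the 1 such pair among 2865 pairs across groups. Wild-type betamethasone 23 had its closest matches in the mutant control group at 3 amplicons, and mutant control 23 in the wild-type betamethasone group at 5. Within a group, 4 pairs matched at 4 amplicons, the most of any pair, of 6 or 7 compared.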
